A study of Mus musculus with 6 samples.

How the data were processed

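Total RNA from sorted mouse bone marrow cells was labelled with biotin and read on Illumina bead arrays, 1 sample per array. The labels give 2 groups of 3 samples each. Granulocytic progenitors (GP) were the Ly6C low cells, and monocyte-like precursors of granulocytes (MLPG) were the Ly6C high cells. Ly6C is a surface antigen that is high on classical monocytes. Nothing in the labels says whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be in part technical.

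The values used were the normalized probe intensities deposited by the authors, on a linear scale, for 45281 probes. GenomeStudio is named in the submitters' processing notes. Its version, the normalization and any background step are not given in the sources used here. In the deposited values, all 6 columns had the same mean (1501), median (179.3), minimum (88.2) and maximum (71670), so the deposited intensity values had been quantile normalized across arrays. No values lay near 0, so the background seen by the scanner remained in them, and fold changes of dim probes are compressed towards 1. A second deposited table heads its 6 signal columns and 6 detection p-value columns by sample numbers that match no sample's labels. These 12 columns were not used here. The plan had been to normalize raw signals with limma's neqc method and to filter on detection p-values. The plan's fallback, the deposited values on a log2 scale, took its place.

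Gene symbols came from the platform's probe annotation. Of all probes, 34885 had 1 symbol, 18 had several and 10378 had none; probes with several symbols were not named. Entrez gene identifiers of 34807 probes matched a table of mouse genes from the assembly GRCm38.p6, and 0 symbols changed. No genome build is named for the array, so no coordinates are given. Probes were kept where the mean log2 value over the 6 arrays was above the median of all probes, 7.48, which left 22640 probes. The probe with the highest mean stood for a gene, and a probe without a symbol stood for itself. This gave 15440 features, 11348 named genes and 4092 unnamed probes. Of 4644 genes with several kept probes, 0 had one probe above 0.5 and another below -0.5 in log2 difference. Mag was the only called gene whose probes differed in sign, at -1.11 and 0.04, and was named for that after its values were seen.

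Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, on log2 values, MLPG minus GP, over all 6 arrays and without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a second count required an absolute log2 difference of at least 1. The tests, the fallback, the gene lists and the rule for named genes were fixed before the data were examined. There were 33 lists, of granule, neutrophil, monocyte, transcription factor, cell cycle, metabolic and immune genes, of markers of other marrow cells, and of handling stress. The 32 lists with at least 5 measured genes were tested with limma's camera, with a preset correlation of 0.01 between genes, and were called at an adjusted p under 0.05. The list of plasma cell markers had 4 measured genes and was not tested. Camera with a correlation estimated for each list and fry, a rotation test of a list alone, were run as alternatives.

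Genes to be named were set by a rule. It took every measured sort marker, and the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap. It left out unnamed probes and symbols that look like clone or predicted-gene identifiers. From each other list it took the 4 members with the smallest p, and any measured member of the lists of transcription factors, suppressor cell genes, chemokine receptors, retinoblastoma and E2F genes and NADPH oxidase genes. Which of the genes the rule allows are named was decided after their values were seen, and some were left out after the alternatives had been run. A gene named outside this rule is said to be so.

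Replicate numbers in the labels run from 1 to 3 in both groups. Deviations from the group means, over all features, correlated between same-numbered GP and MLPG arrays at 0.38 for number 1, 0.30 for number 2 and 0.47 for number 3, all above the minimum of 0.1 set for a pairing. This pairing comes from the data and not from a statement in the labels. Deviations were taken from each group's own mean, so the 3 correlations are not independent of each other. A fit with the replicate number as a block was therefore run only beside the main one. Its values are given where a call changed or a count moved by more than 1.5 times. The same arrays served to choose the block and to fit it, so p-values with the block may be too small.

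Tests were tried on simulated arrays with the real means and spreads of the MLPG against GP comparison. Of the 15440 simulated features, 200 were changed, 50 at each size. The gene test recovered 50% of those changed 1.5-fold, 86% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold, and 13 of 180 calls were unchanged features. Camera called 5 of 5 lists of 20 genes shifted by 0.5 on the log2 scale and 0 of 15 unshifted ones. Simulated genes were independent of each other, so false calls of lists whose genes move together were not tried. Alternatives covered background correction, normalization, the probe filter, the probe for a gene, the variance model, array weights, the replicate block and the omission of each array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Precision is limited by the number of arrays.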

Results

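The series compared gene expression in 2 populations sorted from mouse bone marrow by Ly6C: granulocytic progenitors (GP, Ly6C low, n = 3) and monocyte-like precursors of granulocytes (MLPG, Ly6C high, n = 3). The series title links MLPG to polymorphonuclear suppressor cells in cancer, and the comparison asks how the Ly6C high precursors differ from the Ly6C low ones. Values are normalized probe intensities, given as mean ± SD of 3 arrays, and differences are log2, MLPG minus GP. The median difference over all features was 0.01. On the first principal component, which held 49.6% of the variance, the GP arrays lay at -30.1, -6.37 and -13.1 and the MLPG arrays at 12.37, 15.02 and 22.23.

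In MLPG, 5 of 8 measured eosinophil markers were lower than in GP and 1 was higher, 5 of 29 mature neutrophil genes were lower, and a smaller set was higher that included the monocyte transcription factor Klf4 and the cathepsin Ctsc. The intensity of Prg2, the eosinophil major basic protein, was 61180 ± 14400 in GP and 4029 ± 1500 in MLPG (n = 3), 15.5-fold higher in GP on a probe whose GP values reached near the highest value on the arrays, 71670, where a larger fold cannot be read. Mmp9, a gelatinase of late neutrophil granules, was at 7941 ± 2890 in GP and 1289 ± 431 in MLPG, 6.14-fold higher in GP. Klf4 was at 725 ± 273 in GP and 2498 ± 353 in MLPG, 3.58-fold higher in MLPG. Ctsc, which activates the serine proteases of primary granules, was at 4549 ± 735 in GP and 12780 ± 1310 in MLPG, 2.83-fold higher in MLPG.

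In all, 79 of 15440 features passed the gene test (limma, adjusted p under 0.05), 22 higher and 57 lower in MLPG, and 50 of them differed at least 2-fold, 14 higher and 36 lower. At an unadjusted p under 0.05 there were 2262 of the 15440. Counts of list members at that threshold are to be read against this share. Of the 79, 59 were named genes, and in all 79 the values of the groups did not overlap. Non-overlap held for 3145 features, 20.4%, against 10% by chance if the 6 arrays are exchangeable, which paired arrays are not. With the replicate block 630 features were called, 230 higher and 400 lower, and all 79 were among them. The pairing behind the block was read from these same arrays, so counts with the block may be too high. At least 2-fold, 140 were called with the block, 52 higher and 88 lower. The blocked count was 2056 without pair 2 and 6 without pair 3. The number of calls depended on single arrays: it was 348 without GP replicate 2, 25 without GP replicate 3, and 2, 3 and 2 without MLPG replicates 1, 2 and 3, of which Prg2 and 1 unnamed probe were called in each. The other genes named here as higher or lower therefore each lost their call without at least 1 array. The log2 differences lay between 1.61 and 2.13 for Klf4, 1.28 and 1.62 for Ctsc, and -3.05 and -2.27 for Mmp9 over all alternatives.

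**Figure D1:**
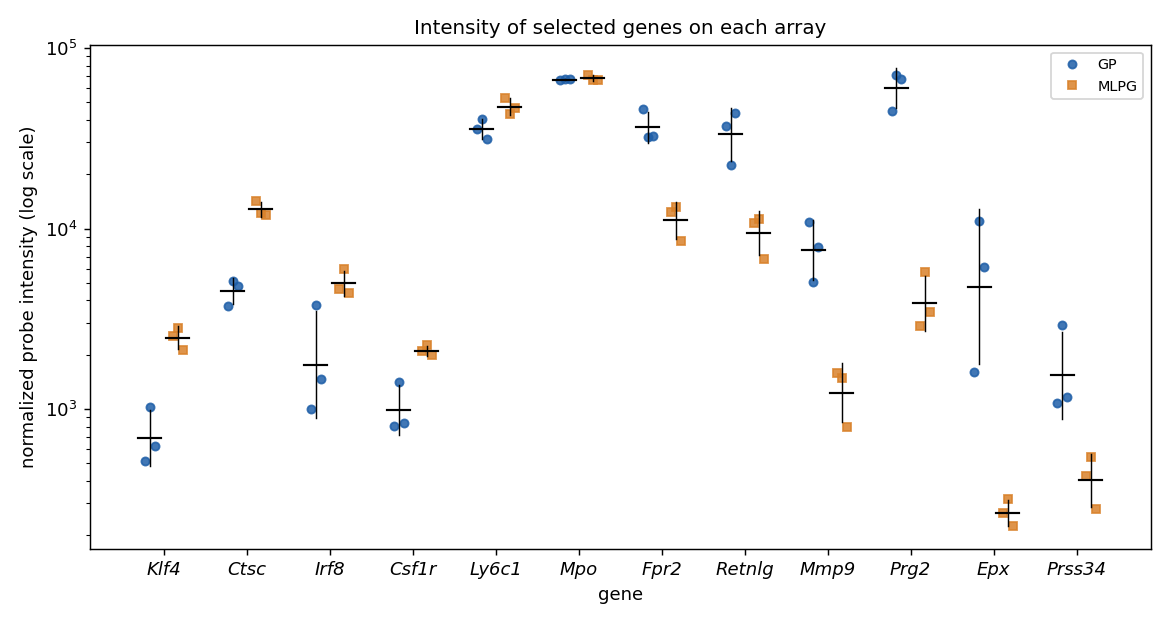
Normalized probe intensity (log scale) of 12 genes on each of the 3 GP arrays (circles) and 3 MLPG arrays (squares); horizontal lines are means of log2 values and vertical lines are ± 1 SD of log2 values. Prg2 lies between 44668 and 71154 in GP and between 2888 and 5726 in MLPG, while the groups overlap for Mpo.

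Ly6c1, 1 of the genes of the antigen used for the sort, was at 35790 ± 4440 in GP and 47580 ± 5060 in MLPG, a log2 difference of 0.41 that did not pass the test (adjusted p = 0.20 in limma and 0.10 with the replicate block). Its 1 probe lay above 15 on the log2 scale in both group means, near the top of the scale, so the size of this difference is uncertain. Csf1r, the receptor of macrophage colony-stimulating factor, differed by 1.10 (adjusted p = 0.072 in limma and 0.010 with the block). Itgam, the integrin chain CD11b, differed by -0.63 (adjusted p = 0.079 in limma and 0.025 with the block). The differences of Kit and Cd14 were -0.19 and 0.01, with adjusted p of 0.73 and 0.99 (limma).

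Among called genes with a usable symbol, the largest increases in MLPG behind Klf4 and Ctsc were of Trem2, a receptor of myeloid cells, by 2.60-fold, Rassf4 by 2.44-fold and Rnase2a by 2.38-fold. Btla, an inhibitory receptor of lymphocytes and myeloid cells, rose by 2.34-fold, Nrg1 by 2.25-fold and Itga1 by 2.11-fold. Met, the receptor of hepatocyte growth factor, rose by 1.92-fold, Mfsd7a by 1.89-fold, Thbd, which encodes thrombomodulin, by 1.87-fold, and Cysltr1, a leukotriene receptor, by 1.81-fold. Adjusted p of these 12 genes lay between 0.0123 (Ctsc) and 0.0434 (Rassf4). Means of Met, Itga1 and Rnase2a in GP, at 154, 169 and 176, lay below the median of all probes, 179.3. A dimmer probe of Nrg1 differed by 0.084, and with the mean of its probes Nrg1 differed by 0.63 and was not called (adjusted p = 0.073, within a range of 0.00016 to 0.16 over all alternatives). Dimmer probes of Mfsd7a differed by 0.59 and 0.44, and the dimmest of Rassf4 by 0.60. C1galt1c1, the chaperone of an O-glycosylation enzyme, was higher in MLPG by 2.37-fold (adjusted p = 0.0092, limma). The naming rule read its symbol as a clone identifier, and it was chosen after its values were seen. Of the called probes without a symbol, 1 was at 237.7 ± 77.1 in GP and 2805 ± 1650 in MLPG, 10.99-fold higher in MLPG (adjusted p = 0.018, limma), and others were higher by 4.43-fold, 3.07-fold and 2.61-fold, all chosen after their values were seen.

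Among called genes with a usable symbol, the largest decreases in MLPG were of eosinophil-associated genes. GP exceeded MLPG by 36.4-fold for Ear6, 20.2-fold for Prg3, 17.8-fold for Epx, the eosinophil peroxidase, 15.7-fold for Ear3 and 10.4-fold for Ear10. Adjusted p of the 12 largest decreases among these called genes lay between 0.0034 (Prg2) and 0.038 (Gata2). Ear6, Ear3 and Ear10 are near-identical ribonuclease genes whose probes may read one another, so their separate values are uncertain. Values of Ear3, Ear6, Prg2, Retnlg and Fpr2 reached above 15 on the log2 scale in GP, near the top of the scale, so their folds and ranks are uncertain as well. Dimmer probes of Ear3 differed by -3.20 and -2.73, against -3.97 on the brightest. Called probes without a symbol, chosen after their values were seen, were higher in GP by up to 19.4-fold. Of the 8 measured eosinophil markers, 5 were lower (Prg2, Prg3, Epx, Ear6 and Ear10), 1 was higher (Rnase2a) and 2 did not pass. Adjusted over the list alone, 7 were lower and 1 was higher. With the block 6 were lower, Alox15 among them (log2 difference -2.45, adjusted p = 0.11 in limma and 0.023 with the block), which was chosen after its values were seen. The list was shifted down, with a median of -3.67 (camera adjusted p = 9.1e-08; adjusted p = 0.38 with an estimated correlation).

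Mature neutrophil genes were lower in MLPG as a group. All 29 measured members had a difference below 0, with a median of -0.60 (camera adjusted p = 4.3e-15; adjusted p = 0.34 with an estimated correlation), and 5 of the 29 fell. Besides Mmp9, these were Retnlg, which encodes a resistin-like protein, 3.53-fold higher in GP, Fpr2, a formyl peptide receptor, 3.26-fold higher, the membrane-bound metalloproteinase gene Mmp25, 2.48-fold higher, and the glucose transporter gene Slc2a3, 1.75-fold higher. Mmp25 was named after its values were seen. Adjusted over the list alone, 14 of the 29 were lower, and 14 were lower with the block. Cxcr2, the chemokine receptor by which neutrophils leave the marrow, was at 8254 ± 1810 in GP and 4037 ± 401 in MLPG (adjusted p = 0.054 in limma and 0.016 with the block). Outside this list, the decreases named by the rule were of Asprv1, 4.83-fold higher in GP, Scrg1, 3.63-fold higher, Slfn1, 3.44-fold higher, and Gata2, 3.44-fold higher.

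Secondary granule genes were shifted down in MLPG (17 of 18 measured genes below 0, median -0.28; camera adjusted p = 6.7e-06, and adjusted p = 0.48 with an estimated correlation), while 0 of the 18 passed the gene test in limma. At an unadjusted p under 0.05 there were 9, adjusted over the list alone 4 were lower, and with the block 4 were lower, among them Orm1 (log2 difference -0.94, blocked adjusted p = 0.0060 in limma), Chil1 (-0.67, 0.038) and Itgb2l (-0.68, 0.017). The Chil1 probe lay above 15 on the log2 scale in both group means, so its difference is uncertain. Primary granule genes were shifted up (11 of 13 above 0, median 0.09; camera adjusted p = 0.0098, and adjusted p = 0.48 with an estimated correlation). Ctsc was the 1 member that rose. Adjusted over the list alone 3 were higher, and with the block 2 were, the other being Gstm1 (log2 difference 0.50, adjusted p = 0.18 in limma and 0.044 with the block). The list median was 0.15 without GP replicate 3 and 0.15 without MLPG replicate 2. In the block without pair 1 it was 0.053 and the list was not called (adjusted p = 0.081, within a range of 0.0014 to 0.48 over all alternatives). The dimmer probe of Gstm1 differed by 0.093. Mpo, which encodes myeloperoxidase, was at 67050 ± 777 in GP and 68120 ± 2510 in MLPG, and Elane, neutrophil elastase, at 67780 ± 482 and 70200 ± 728, near the highest value on the arrays, 71670. Both genes, and Ltf, whose brightest probe differed by -0.02, were chosen after their values were seen. A dimmer probe of Ltf differed by -1.22.

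Monocyte genes were shifted up in MLPG (26 of 32 measured genes above 0, median 0.39; camera adjusted p = 6.0e-07, and adjusted p = 0.38 with an estimated correlation). The median lay between 0.28 and 0.64 over all alternatives. None of the 32 passed the gene test over all features (limma, 0 genes, with 19 at an unadjusted p under 0.05). Adjusted over the list alone 13 were higher and 2 lower, and with the block 10 were higher and 1 lower. Ms4a6d was at 1186 ± 415 in GP and 3379 ± 619 in MLPG (adjusted p = 0.054 in limma and 0.015 with the block), and Pld4 at 1172 ± 517 and 3705 ± 1030 (0.077 and 0.017). Of 19 monocyte and dendritic transcription factors, Klf4 rose and 18 did not pass. With the block Irf5 (log2 difference 1.61, adjusted p = 0.061 in limma and 0.013 with the block), Irf8 (1.49, 0.18 and 0.021) and Pou2f2 (0.74, 0.086 and 0.016) were also called. The list of these factors had a camera adjusted p of 0.065, and of 0.042 with the block, but of 0.48 with an estimated correlation and of 0.58 with both. The list was called in 8 of 20 alternatives, among them those without GP replicate 1 (0.036), GP replicate 2 (0.015), MLPG replicate 1 (0.031) or MLPG replicate 3 (0.034). The range was 0.0016 to 0.48 over all 20 alternatives, none of which joins the block and an estimated correlation.

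Irf8, a factor needed for monocyte development, was at 997, 3765 and 1461 on GP arrays 1 to 3 and at 4646, 5969 and 4413 on MLPG arrays 1 to 3. Granulocyte transcription factors showed no call (0 of 22 genes, limma, 4 at an unadjusted p under 0.05; camera adjusted p = 0.51). The list's median was 0.003, or -0.014 with cyclic loess normalization, while its mean, -0.04, and its test pointed down. With the block 1 was higher and 1 lower. Within the list, Bcl6 differed by -0.63 (adjusted p = 0.12 in limma and 0.016 with the block), Cebpe by -0.25 (0.38) and Cebpa by 0.16 (0.53). Dimmer probes of Cebpe differed by -0.38, -0.33 and -0.36 (unadjusted p = 0.013, 0.10 and 0.093, limma). The Cebpa difference lay between 0.10 and 0.27 over all alternatives. Gfi1, a repressor needed for neutrophil development, was at 12620 ± 78.1 in GP and 12440 ± 3390 in MLPG (adjusted p = 0.92, limma).

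**Figure D2:**
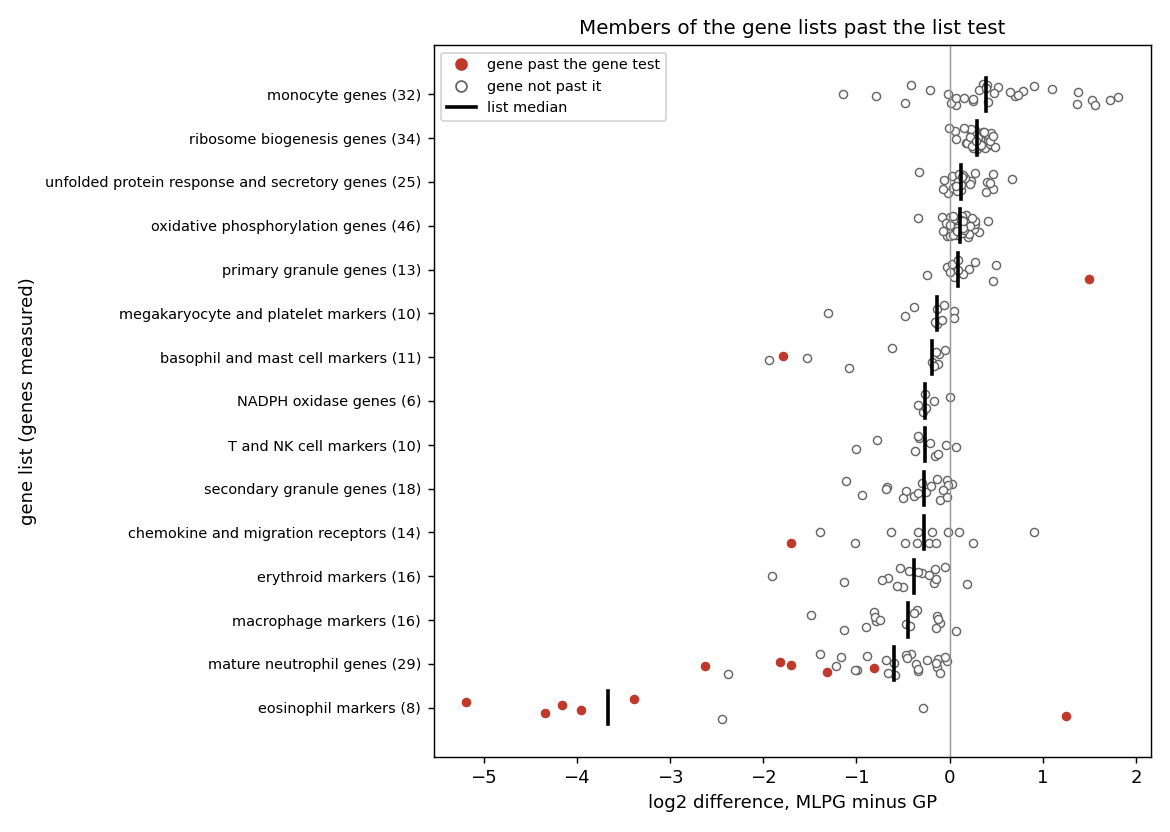
Log2 differences, MLPG minus GP, of the members of the 15 gene lists past the list test; each point is a gene, filled where it passed the gene test, bars are list medians, and numbers in brackets are measured genes. Eosinophil markers have the lowest median, -3.67, and all 29 mature neutrophil genes lie below 0.

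Ribosome biogenesis genes were shifted up in MLPG (33 of 34 measured genes above 0, median 0.30; camera adjusted p = 7.4e-08, and adjusted p = 0.49 with an estimated correlation). The gene test in limma called 0 of the 34, with 8 at an unadjusted p under 0.05 and 0 with the block. The list median was 0.13 without GP replicate 1. Nob1, which acts in small-subunit maturation, was at 1839 ± 297 in GP and 2560 ± 62.7 in MLPG, and Pes1 at 1280 ± 185 and 1731 ± 49.8. Oxidative phosphorylation genes (40 of 46 above 0, median 0.11; camera adjusted p = 0.00040, and adjusted p = 0.48 with an estimated correlation) and unfolded protein response and secretory genes (21 of 25 above 0, median 0.13; camera adjusted p = 0.011, and adjusted p = 0.49 with an estimated correlation) were also shifted up. In these 2 lists, limma called 0 genes, with 6 of 46 and 5 of 25 at an unadjusted p under 0.05, beside 2262 of 15440 features in all. With the block 2 were called in the latter, the chaperone gene Hyou1 (log2 difference 0.67, blocked adjusted p = 0.014) among them. The unfolded protein response list was not called without GP replicate 1 (median 0.05, adjusted p = 0.13) or MLPG replicate 3 (0.04, 0.084), nor with array quality weights (0.08, 0.083), within a range of 0.00090 to 0.49 over all alternatives, and its median was 0.19 without GP replicate 2.

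Cell cycle genes were not called as lists with all 6 arrays. The medians were 0.02 for 40 S phase genes (camera adjusted p = 0.59) and 0.02 for 40 G2/M genes (0.65), and limma called 0 genes in both, with 2 and 3 at an unadjusted p under 0.05. Without GP replicate 1, G2/M genes were called, with a median of 0.13 (adjusted p = 0.00022, the lowest in a range up to 0.92 over all alternatives). Histone genes (median -0.03, camera adjusted p = 0.54) and glycolysis genes (-0.03, 0.47) were not called either, and neither was the retinoblastoma and E2F family (-0.12, 0.59), whose median was -0.055 without GP replicate 2, -0.061 without MLPG replicate 1 and -0.063 without MLPG replicate 3. Slc2a3 was the 1 glycolysis gene that fell. Rb1 was at 11670 ± 2370 in GP and 9574 ± 784 in MLPG (adjusted p = 0.47, limma), and E2f6 at 3003 ± 44.0 and 3992 ± 77.2 (0.080, and 0.042 with the block). A dimmer probe of Rb1 differed by -0.38 (unadjusted p = 0.017, limma), against -0.27 on the brightest. With the block 2 members of the retinoblastoma and E2F family were higher, and adjusted over the list alone 1 was.

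Genes of suppressor cells were not called as a list (21 measured, median -0.10; camera adjusted p = 0.51), with 0 called in limma and 4 at an unadjusted p under 0.05. The median lay between -0.058 and -0.043 without any 1 of GP replicates 1, 2 and 3 and MLPG replicates 1 and 3. With the block 1 was higher and 1 lower, and adjusted over the list alone 1 was lower. Arg2, an arginase, was at 792 ± 316 in GP and 257 ± 48.6 in MLPG (adjusted p = 0.066 in limma and 0.024 with the block). S100a8 was at 67880 ± 353 in GP and 65640 ± 567 in MLPG, near the top of the scale. NADPH oxidase genes were shifted down (6 of 6 below 0, median -0.26; camera adjusted p = 0.022, and adjusted p = 0.48 with an estimated correlation), with 0 genes called in limma and 3 at an unadjusted p under 0.05. That call was lost without GP replicate 1 (median -0.15, adjusted p = 0.083), GP replicate 3 (-0.25, 0.088) or MLPG replicate 2 (-0.25, 0.060), within a range of 0.0044 to 0.48 over all alternatives. Chemokine and migration receptors were shifted down as well (11 of 14 below 0, median -0.28; camera adjusted p = 0.0012, and adjusted p = 0.48 with an estimated correlation), with Fpr2 the 1 called member. Adjusted over the list alone 1 was higher and 5 lower, and with the block 1 was higher and 4 lower, while the median was -0.14 without GP replicate 1. Ccr2, the monocyte chemokine receptor, differed the other way, by 0.91 (adjusted p = 0.11 in limma and 0.040 with the block).

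Markers of other marrow cells were lower in MLPG in several lists, the same direction as the neutrophil and eosinophil genes. The lists did not follow 1 pattern over pairs 1 to 3, with medians of -2.23, -3.81 and -4.29 for eosinophil and -1.27, -0.05 and -0.23 for macrophage markers. Basophil and mast cell markers were shifted down (11 of 11 below 0, median -0.19; camera adjusted p = 8.6e-06, and adjusted p = 0.34 with an estimated correlation), with Gata2 the 1 called member. There were 5 lower adjusted over the list alone, and the median was -0.38 without MLPG replicate 2 and -0.30 without MLPG replicate 3. With the block Prss34, a basophil protease, also passed, at 1725 ± 1040 in GP and 417 ± 131 in MLPG (adjusted p = 0.089 in limma and 0.0047 with the block), as did Cpa3 (0.094 and 0.014) and Fcer1a (0.073 and 0.030). Erythroid markers (15 of 16 below 0, median -0.39; camera adjusted p = 5.4e-06, and adjusted p = 0.48 with an estimated correlation) had 0 called genes in limma, 9 at an unadjusted p under 0.05, and 6 lower with the block, Slc4a1 among them (-1.13, adjusted p = 0.016 with the block, and a difference of -0.68 without MLPG replicate 3). Macrophage markers (15 of 16 below 0, median -0.44; camera adjusted p = 0.0012, and adjusted p = 0.52 with an estimated correlation), T and NK cell markers (9 of 10 below 0, median -0.27; 0.0018 and 0.34) and megakaryocyte markers (8 of 10 below 0, median -0.13; 0.042 and 0.38) were also lower as lists, with 0 genes called in limma and 2, 3 and 1 at an unadjusted p under 0.05. With the block 0 macrophage, 1 T and NK cell and 2 megakaryocyte markers were lower, and adjusted over the list alone 0, 1 and 1. The T and NK cell median was -0.11 without the filter on dim probes. Without GP replicate 1 the macrophage median was -0.07 and the list was not called (adjusted p = 0.068, within a range of 4.3e-07 to 0.52 over all alternatives), and without GP replicates 2 and 3 it was -0.69 and -0.71. The megakaryocyte list was not called without GP replicate 2 (0.071), GP replicate 3 (0.078) or MLPG replicate 3 (0.070), within a range of 0.0026 to 0.38. B lineage markers were not called as a list (9 measured, median -0.01; camera adjusted p = 0.66).

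The list test called 15 of 32 lists in all, 5 up and 10 down, and 17 with the block. Other splits of the 6 arrays into 3 and 3 called between 3 and 13 lists by the same test. Each of these splits held arrays of both groups on both sides, so a true difference between the groups could give list calls there too. The comparison therefore cannot say whether a list call alone sets GP apart from MLPG. Estimated correlations between genes reached 0.72 in the ribosome biogenesis list and 0.69 in the eosinophil list, against the preset 0.01, so the preset adjusted p-values may be too small. No list was called with an estimated correlation (0 lists, 3 at an unadjusted p under 0.05) or by fry (0 lists).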

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

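Alternatives with cyclic loess, the 75th percentile filter, the brightest probe below 15 on the log2 scale, and the block without a replicate pair were chosen after seeing the data; the others were planned. Background correction and normalization from raw signals and the detection filter were not run, because the raw columns match no sample. For the genes and lists named in the text, the replicate block changed no call other than those given beside the results or counted per list. Gene calls depended on single arrays: leaving out 1 array gave between 2 and 348 called features (0 to 162 higher, 2 to 186 lower) and between 2 and 138 at least 2-fold (0 to 67 higher, 2 to 71 lower), with fewer samples as 1 cause. Without GP replicate 2 all 79 were called, without GP replicate 1, 55, and without GP replicate 3, 23. Prg2 was called in all 19 alternatives that gave it a test. Counts of called lists ranged from 13 to 16 without 1 array, although the macrophage, NADPH oxidase, unfolded protein response and megakaryocyte lists each lost their call without at least 1 array, and from 10 to 18 in the other alternatives of the preset test. In all, 0 lists passed with an estimated correlation and 0 with fry, which does not compare a list with other genes. Megakaryocyte markers were not called with cyclic loess (adjusted p = 0.055), nor macrophage markers above the 75th percentile (0.24), nor NADPH oxidase genes in the block without pair 1 (0.060), in ranges of 0.0026 to 0.38, 4.3e-07 to 0.52 and 0.0044 to 0.48 over alternatives. Among values of the genes followed through the alternatives, 1519 kept their side of the threshold, 187 passed it, 133 lost it and 14 reversed; among lists, 534, 22, 44 and 31. Array signal over background limits dim genes, and the brightest probes lie near the top of the scale.

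Without the filter 146 features were called (51 higher, 95 lower, 25 at least 2-fold higher), with more features tested. With every probe on its own 34 were higher and 24 at least 2-fold higher, and with an intensity trend and robust prior 34 were higher. Array quality weights gave 220 (79 higher, 141 lower), and 96 at least 2-fold (36 higher, 60 lower). The replicate block gave 630 (230 higher, 400 lower), and 140 at least 2-fold (52 higher, 88 lower). The block without pair 1 gave 465 (152, 313), and 131 at least 2-fold (35, 96). Without pair 2 it gave 2056 (1051, 1005), and 222 at least 2-fold (78, 144). Without pair 3 it gave 6 (1, 5), and 6 at least 2-fold (1, 5). Above the 75th percentile 10 were higher and 7 at least 2-fold higher, with fewer genes tested. Otherwise the cause was not tested.

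Reversed values, none called in either setting, lay between -0.30 and 0.18. The median of granulocyte transcription factors was -0.020 without the filter, -0.041 with the mean of probes, -0.011 with array weights, -0.014 with cyclic loess, -0.050 above the 75th percentile and -0.027 with the block without pair 1. Conventional dendritic cell markers were at 0.0047 without the filter. With array weights sort markers were at -0.021, histone genes at 0.0061, stress genes at -0.065 and Cd14 at -0.11. With cyclic loess sort markers and Cd14 were at -0.0050 and Mpo at -0.00017. In the block without pair 1, stress genes were at -0.061 and Mpo at -0.017. Without pair 2, G2/M genes were at -0.047, class II genes at 0.044, stem cell genes at 0.028, Kit at 0.0018, Gfi1 at 0.17 and Cd14 at -0.30, and without pair 3 G2/M genes were at -0.037. Leaving out 1 array gave ranges of -0.050 to 0.13 for G2/M, -0.20 to 0.047 for stem cell, -0.048 to 0.0085 for glycolysis, -0.26 to 0.12 for class II, -0.086 to 0.14 for stress, -0.12 to 0.067 for histone and -0.0084 to 0.048 for S phase genes. The ranges were -0.027 to 0.039 for granulocyte transcription factors, -0.22 to 0.17 for sort markers, -0.39 to 0.033 for Kit, -0.24 to 0.17 for Cd14, -0.0081 to 0.039 for Mpo, -0.23 to 0.18 for Gfi1 and -0.045 to 0.0043 for Ltf. The cause was not tested.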

Other observations

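Tests on eosinophil genes and on granule genes, and the comparison of monocyte genes with random lists, were chosen after the result was seen. Class II antigen presentation genes did not move together (11 measured, median -0.06, 5 above 0 and 6 below 0; camera adjusted p = 0.59), and 0 passed in limma, with 8 at an unadjusted p under 0.05. Adjusted over the list alone 4 were higher and 4 lower, and with the block 1 was higher and 4 were lower. The peptide-presenting chain gene H2-Aa was at 440.3 ± 170 in GP and 158.7 ± 28.0 in MLPG (adjusted p = 0.094 in limma and 0.013 with the block), and the invariant chain gene Cd74 at 767.1 ± 266 and 357.3 ± 156 (0.24 and 0.0058). The Cd74 difference was -1.14, and -0.75 without MLPG replicate 3.

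Interferon response genes had a median of -0.13 (28 measured, 18 below 0; camera adjusted p = 0.090, and 0.025 with the block, but 0.67 with an estimated correlation and 0.68 with both), with 0 called in limma and 5 at an unadjusted p under 0.05. With the block 1 was higher and 3 lower. The list was also called without GP replicate 2 (0.0025) or MLPG replicate 3 (0.034), without the filter (0.041) and with array quality weights (0.014), within a range of 0.0025 to 0.67 over all 20 alternatives, none of which joins the block and an estimated correlation. Its median was -0.079 without GP replicate 1, -0.045 without GP replicate 3 and -0.063 without MLPG replicate 2. The guanylate-binding protein gene Gbp3 differed by 1.08 (adjusted p = 0.16 in limma and 0.026 with the block), while Oas3, an antiviral enzyme gene, differed by -0.71 (0.23 and 0.044), and by -0.44 without GP replicate 3. Markers of plasmacytoid dendritic cells (median -0.13, camera adjusted p = 0.12), conventional dendritic cells (-0.07, 0.20), and stromal and endothelial cells (-0.09, 0.47) were not called with all 6 arrays. Neither were stem and early progenitor genes (-0.11, 0.24), in which Gata2 was the 1 called gene, nor handling stress genes (0.03, 0.59). Without GP replicate 1 the plasmacytoid list (0.019, in a range of 0.010 to 0.57) and the stem cell list (0.012, in a range of 0.0021 to 0.89) were called. The plasmacytoid median was -0.0036 without GP replicate 2, -0.042 without MLPG replicate 1 and -0.086 without MLPG replicate 2, and the stromal median was between -0.046 and -0.023 without GP replicate 1 or 2 or MLPG replicate 3. The conventional dendritic cell median was -0.040 without GP replicate 2 and -0.041 without MLPG replicate 3. With the block 1 plasmacytoid and 2 conventional dendritic cell markers were lower, 1 stromal marker was higher, 1 stem cell gene was higher and 1 lower, and 2 stress genes were higher and 1 lower. Sort and label markers as a list had a camera adjusted p of 0.63. In pairs 1 to 3 the median of ribosome biogenesis genes was 0.55, 0.04 and 0.29, and that of macrophage markers -1.27, -0.05 and -0.23.

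Eosinophil genes were lower in MLPG, and cross-reading among near-identical Ear genes alone was argued against by Prg2, Prg3 and Epx, whose median difference was -4.16. A lower purity of the GP sort that raised every other cell type alike was examined with 24 markers of other cell types. They lay at no less than 2 times the median of all probes in GP and no more than 3 times in MLPG. Their median was -0.76 (quartiles -1.15 and -0.42), against -3.67 for eosinophil markers (-4.20 and -1.91). This gap cannot decide the question. A marker dim in GP and near the background in MLPG, such as Itga2b at 482.5 and 181.5, cannot fall far. All 24 were lower, 10 of them by at least 1, which the bounds on their level in GP and MLPG favour. The T and NK (-0.27), basophil and mast (-0.19), erythroid (-0.39), macrophage (-0.44) and megakaryocyte (-0.13) lists were themselves called lower. That is the direction a less pure GP sort would give. None was called with an estimated correlation (adjusted p = 0.34 to 0.52, camera), and macrophage markers were not called without GP replicate 1 (median -0.067). A lower purity, alike or unequal between cell types, therefore remains open. Eosinophil-lineage cells in the GP sort may be a candidate source, but 62.5% of the list (5 of 8 genes) was lower by at least 1 in every pair, between the bounds set, with Prg2 at 61180 in GP and 0 of the 8 genes in another list. This source and eosinophil gene expression in the GP themselves cannot be told apart in bulk RNA, and the labels describe only the Ly6C sort as parting the groups.

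Of 17 granule genes above 15 on the log2 scale, 0 passed in limma on their brightest probe, with 4 at an unadjusted p under 0.05 and 1, Chil1 (-0.67), called with the block. A dimmer probe was there for 7, and 4 of these showed a larger difference there. The median gain over all 7 was 0.11. Ltf had the widest gap, -0.02 against -1.22. A signal near the upper end of the scale may hide differences in such genes, but cannot be told apart from unequal probes with 7 genes. A true lack of difference between the groups remains open as well.

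Monocyte genes in GP replicate 2 lay towards MLPG in 27 of 32 genes, with a slope of 0.557 on the MLPG difference (1-sided permutation p = 1e-05, the smallest that 100000 permutations can give). A share of monocyte-lineage cells in that array may be a source, but the slope over all features was 0.459 and that of monocyte genes lay at the 47.3 percentile of 10000 random lists. Slopes with no array in common were 0.184 and 0.910. This source therefore cannot be told apart from a shift of the whole array or from the shared GP arrays. Deviations of GP replicate 2 and MLPG replicate 2 correlated over these genes at 0.483, the direction that a difference shared by the arrays numbered 2 would give. Over all features they correlated at 0.297, and the value of 0.483 was not compared with random lists. It is therefore not shown to be particular to monocyte genes. Genes are not independent replicates, and a biological difference between the samples was not tested.

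The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 79 features, 50 at least 2-fold and 15 lists, and the highest other splits 0, 0 and 13, so that 1 of 10 splits gave as many in each case. Of the splits, 4 part all 3 replicate pairs, and the highest of the others among these called 0 features and 9 lists. With the replicate block the real split called 630 features and 17 lists and the highest other 0 and 13. Every other split holds arrays of both groups on both sides, which puts the GP against MLPG difference into the spread within a side. Fewer gene calls are to be had there whether or not the real counts are too high, so the 0 does not measure false calls. Part of that difference can also give list calls there.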
